A study of Mus musculus with 10 samples.

How the data were processed

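The series measured gene expression in mouse cells on 10 Affymetrix arrays, each hybridised with biotin-labelled RNA from 1 sample. Per the labels, 3 arrays held induced pluripotent stem (iPS) cells made from adult brain neural stem cells (NSC) with a retroviral vector carrying Oct4 alone, 3 held NSC differentiated from such iPS cells, and 4 held NSC derived from adult mouse brain. The groups were taken from the sample titles. The mice carried a fluorescent reporter of Oct4 and a ubiquitous marker gene. Per the labels' protocols, iPS cells were grown on irradiated mouse embryonic fibroblasts in medium with leukaemia inhibitory factor (LIF), total RNA was treated with DNase, and 1 microgram of it entered a single round of labelling.

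The authors deposited a table of log2 expression values per probe set, made with RMA in Bioconductor per the submitters' processing notes and the labels; the RMA version is not given in the sources used here. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of each probe set on the log2 scale. A shift shared by most genes of a group would therefore be largely removed from these deposited values, and differences between dim genes are compressed. Scanner files, scan dates and slide positions were not used here, so the background correction was not varied. Arrays have no read depth, and their number limits the precision.

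The table held 45101 probe sets, of which 64 were control probe sets. Gene symbols came from the platform annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 had none there. Of the 34945, 34741 were found by their Entrez identifier in a RefSeq gene table of the mouse assembly GRCm38.p6, which changed 0 symbols and also gave the chromosome of each gene. Each of the 18193 genes was represented by its brightest probe set, the one with the highest mean over the 10 arrays. Probe sets with several symbols or none were left out of the gene tests.

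Differences were fitted with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, in a layout of the 3 groups over all 10 arrays. This leaves 7 residual degrees of freedom, to which eBayes added 5.95 prior ones. P values are two-sided and adjusted with the Benjamini-Hochberg method over the 18193 genes of a comparison. A gene was called when its adjusted p was under 0.05 and its difference at least 2-fold. Errors of differences are the moderated standard errors (SE) of limma. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

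The test, the thresholds, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the factors Pou5f1, Sox2, Klf4 and Myc; the 5 largest rises and 5 largest falls among called genes whose arrays did not overlap between the groups; the 2 called members with the largest difference in each list of main interest for that comparison; and the 1 such member of every other list. It gave 79 genes. Genes named outside the rule are said to be chosen after their values were seen.

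The 35 lists held 536 members, 518 of them distinct, and 503 entries were measured under a gene symbol. The other 33 were not matched, as the platform annotation used here gives no probe set their symbol alone. A member was matched by its current symbol, and by an older name only where no gene now bears that symbol. This last condition was added after the values had been seen, when H19 and Gpi1 proved to have been matched to other genes through old names; both now count as not matched. The lists covered reprogramming factors, pluripotency, neural stem cells, neurons, astrocytes, the oligodendrocyte lineage, forebrain patterning, hindbrain and spinal cord patterning, feeder fibroblasts, epithelial and mesenchymal genes, DNA methylation and chromatin regulators, the germline, the primed epiblast, mesoderm and endoderm, trophectoderm, imprinted genes, X inactivation RNAs, Y-linked genes, MHC class I and antigen processing, the interferon response, microglia and macrophages, endothelium and pericytes, ependyma, the cell cycle, CDK inhibitors and p53 targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, the Notch, Wnt, BMP and Id, Hedgehog and LIF pathways, and immediate early and stress genes.

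Each list was tested against the other genes with limma's camera, at a preset correlation between genes of 0.01, adjusted over the 35 lists of a comparison, and again with an estimated correlation. A list passed where its adjusted p was under 0.05. The counts of called members were also adjusted over the list alone. Single values of the arrays were compared with exact two-sided permutation tests over all splits, of which 3 against 4 arrays allow 35 and a smallest p of 0.0286, while 3 against 3 allow a smallest p of 0.1.

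The labels give replicate numbers but not whether the samples of a group came from separate cultures or animals. The p values therefore measure the spread between these samples, which may be technical. Of the 45 pairs of arrays, 0 held identical values, and the highest correlation was 0.9983.

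The procedure was tested on simulated data built on the real means and spreads of the 18193 genes, with 50 genes changed by each fold in each comparison. For iPS over brain NSC, 0 of the 50 genes changed 1.5-fold, 22 of those changed 2-fold and 50 of those changed 4-fold were called. For iPS-derived NSC over iPS these counts were 0, 26 and 49, and for iPS-derived NSC over brain NSC 0, 33 and 50. There were 0 calls among unchanged genes. The 2-fold minimum of a call holds down the counts at 1.5-fold and 2-fold. By adjusted p alone, 31, 28 and 27 of the genes changed 1.5-fold passed in the 3 comparisons. Of those changed 2-fold, 49, 45 and 46 passed so, and of the unchanged genes 12, 5 and 5. The position of an array group set on the line between the other groups came out at 0.286 for a true 0.25. The ends came out at 0.102 for a true 0 and 0.929 for a true 1. This check does not cover a group that lies off the line.

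The alternatives were other scalings of the arrays, filters on dim genes, the mean of the probe sets of a gene or every probe set on its own, leaving out probe sets that can cross-hybridise, a fit on the compared groups only, the replicate number as a block, other thresholds, trend, robust and weighted variance models, an estimated correlation for the lists, and leaving out each array in turn. Counts without the genes of chromosome 8 were an alternative chosen after seeing the data.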

Results

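The data were expression values of 18193 genes on 10 arrays: 3 labelled iPS, cells reprogrammed from adult brain neural stem cells with Oct4 alone; 3 labelled iPS-derived NSC, neural stem cells differentiated from such iPS cells; and 4 labelled brain NSC, the neural stem cells derived from adult mouse brain. The design implied 3 comparisons, which ask what changed on reprogramming, what changed on differentiation, and how the differentiated cells differed from the brain cells. Values are deposited RMA values on the log2 scale, given as mean ± SD with the number of arrays, and differences are in log2 units with the SE from limma. The 10 arrays limit the precision.

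The reprogramming factor did not follow the labels. Pou5f1, which encodes Oct4, stood at 13.29 ± 0.25 (SD, n = 3) in the arrays labelled iPS-derived NSC, at 4.67 ± 0.16 (n = 3) in those labelled iPS and at 4.55 ± 0.05 (n = 4) in brain NSC. Whether its probe set also reads the cDNA of the vector is not given in the sources used here. Zfp42, a marker of undifferentiated embryonic stem cells, showed the same order, with 12.44 ± 0.07 against 3.54 ± 0.05 in the arrays labelled iPS, and in brain NSC it was as low. Fabp7, a fatty acid binding protein of radial glia and neural stem cells, ran the other way, with 4.43 ± 0.21 in the arrays labelled iPS-derived NSC, 14.17 ± 0.02 in those labelled iPS and 14.45 ± 0.10 in brain NSC. The neural factor Olig2 stood at 6.53, 12.78 and 12.47. Sox2, which both pluripotent and neural stem cells express, lay between 12.04 and 12.17 in the means of all 3 groups, and Myc between 9.87 and 10.34. These levels contradict the names of the iPS and iPS-derived NSC arrays. The labels were kept as deposited, so every direction given here that involves either of these groups follows labels that the marker genes contradict.

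**Figure D1:**
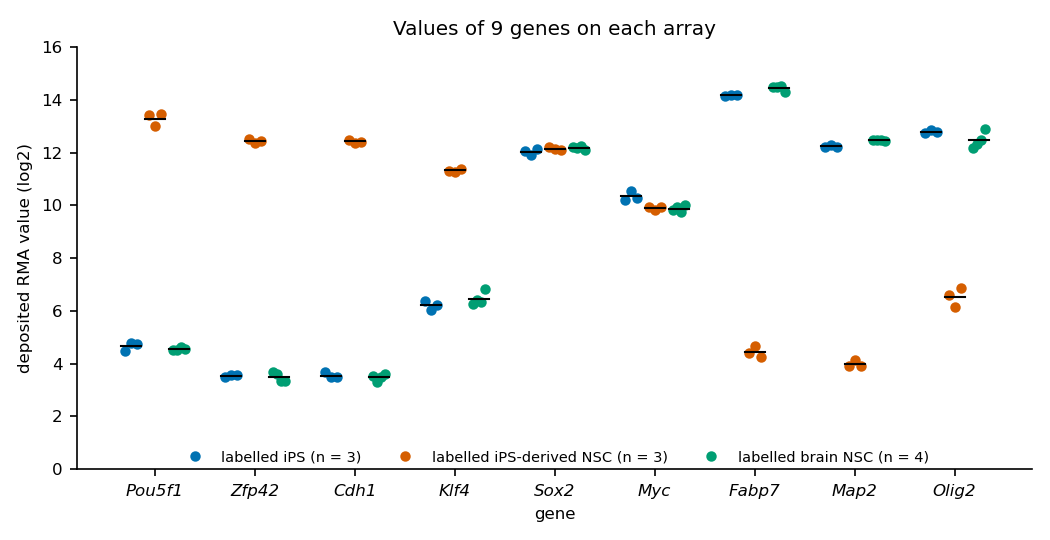
Deposited RMA values (log2) of 9 genes on each array, with a point per array and a bar at the group mean, for the arrays labelled iPS (n = 3), iPS-derived NSC (n = 3) and brain NSC (n = 4). Pou5f1, Zfp42, Cdh1 and Klf4 are high in the arrays labelled iPS-derived NSC (Pou5f1 13.29) and low in both other groups, while Fabp7, Map2 and Olig2 show the opposite order.

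The comparison of iPS with brain NSC asks what changed on reprogramming. In the arrays labelled iPS, 173 genes were called higher and 162 lower than in brain NSC, and the pluripotency genes were not among them. The secreted carbonic anhydrase Car6 rose by 3.04 ± 0.10 (SE), the cell surface glycoprotein Cd93 by 2.80 ± 0.09 (6.96-fold) and Sostdc1, a secreted antagonist of BMP and Wnt signals, by 2.26 ± 0.09, with 3 against 4 arrays. The protocadherin Pcdh7 fell by 4.51 ± 0.18, the Notch effector Hes5 by 3.58 ± 0.19, the interferon-inducible Ifi202b by 3.47 ± 0.11, and the developmental regulator Eya1 by 3.13 ± 0.13, and the zinc finger homeobox gene Zfhx4 fell by 2.99 ± 0.12. Pcdh7 and Zfhx4 averaged 3.32 and 3.92 in the arrays labelled iPS, below the lower quartile of all probe sets there (4.22 to 4.27). The values used here hold no detection calls, so differences from such low levels, in any comparison, are not exact folds. All 8 of these genes had adjusted p values of 7.49e-08 or less. The direction rests on labels that the markers contradict.

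Of the 26 measured pluripotency genes, 0 were called in this comparison, and their mean difference was -0.03 (camera adjusted p = 0.729). The 4 classical reprogramming factors were not called either: Pou5f1 differed by 0.11 ± 0.12, Sox2 by -0.14 ± 0.09, Klf4 by -0.26 ± 0.13 and Myc by 0.47 ± 0.10, the last with an adjusted p of 0.00612 but under 2-fold. Among the 26 neural stem cell markers, 1 fell, which was Hes5. Feeder fibroblast markers (15 measured) and epithelial genes (17 measured) held 0 called members. Of the 16 mesenchymal genes, 2 rose: Twist1, a transcription factor of mesenchyme, by 1.45 ± 0.17 and the growth factor Tgfb2 by 1.35 ± 0.19, though the call of Tgfb2 was lost with the mean of its probe sets (0.91). Rest, a repressor of neuronal genes, was the 1 called member of 21 chromatin regulators at 1.33 ± 0.12, but another of its probe sets gave -0.06.

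Smaller sets of called genes lay in other lists. Lhx2 (1.30 ± 0.17) and Otx2 (1.00 ± 0.16), both homeobox factors of the forebrain, were the 2 called of 17 forebrain patterning genes. Otx2, also the 1 called member of 8 primed epiblast genes, sat at the 2-fold limit. Its call was lost without replicate 2 (0.975) or 3 (0.980) of the labelled iPS group, without brain NSC replicate 1 (0.884) or 4 (0.907), with quantile normalization (0.985) and with the replicate block (0.907). Kit, a receptor tyrosine kinase that germ cells use, rose by 2.15 ± 0.11. Id2 rose by 1.93 ± 0.10 and Id3, chosen after its values were seen, fell by 1.61, both inhibitors of basic helix-loop-helix factors that respond to BMP. The immediate early genes Egr1 (1.35 ± 0.14) and Ier2 (1.11, chosen after its values were seen) were the 2 called of 15. Dhcr7, an enzyme late in cholesterol synthesis, was higher by 1.02 ± 0.28 (adjusted p = 0.0217), a call that leaving out a single array ended for each array of the labelled iPS group and for brain NSC replicates 1 to 3. Apoe, the lipid carrier apolipoprotein E, fell by 1.14 ± 0.17 and S1pr1, a sphingolipid receptor chosen after its values were seen, fell by 1.08, the 2 called of 16 astrocyte markers. The glycolytic enzyme Pfkp fell by 2.08 ± 0.18. Plagl1, an imprinted zinc finger gene, fell by 1.54 ± 0.10 on its brightest probe set, but another probe set gave 0.06.

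The gene list test found 0 of 35 lists past its threshold in this comparison. The lowest adjusted p was 0.145, for the Notch pathway genes, with a mean of -0.46 and 1 called member of 14 (adjusted p = 0.811 with an estimated correlation); it was 0.0326 without brain NSC replicate 3. The highest was 0.993, for the ependymal markers, whose median was 0.05 and mean 0.02 although camera's direction was down; the mesoderm and endoderm genes had a mean and median of 0.00 with camera's direction down. In this and both other comparisons, the counts of called members adjusted over the list alone were the same as those over all genes in each of the 35 lists.

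Together, 335 of 18193 genes (1.84%) were called by limma, and 5919 had an unadjusted p under 0.05. The count was 539 without brain NSC replicate 4, 223 with the mean of the probe sets of a gene and 183 when tested against a minimum of 1.5-fold. Among the named genes, Zbed6 (2.32 ± 0.16 higher, a transcriptional repressor of transposon origin) and the nuclear RNA Malat1 (2.25 ± 0.23 higher) depended on the probe set, since other probe sets gave -0.36 for Zbed6 and -0.89 for Malat1, and Id2 was not called (0.43) without probe sets that can cross-hybridise. Some measures of RNA and array quality moved with these groups too. The difference of the 3-prime from the 5-prime control probe set was 0.57 ± 0.09 (SD, n = 3) in the arrays labelled iPS and 0.32 ± 0.12 (n = 4) in brain NSC for Actb, and -0.065 ± 0.049 and -0.201 ± 0.058 for Gapdh. Neither overlapped between the groups (exact permutation p = 0.0571 each, two-sided; 0.200 adjusted over 12 tests). The mean of all hybridisation controls was 11.006 ± 0.130 and 10.601 ± 0.375 and overlapped between the groups (exact permutation p = 0.200, two-sided, 0.343 adjusted over 12 tests). The hybridisation control bioC alone, chosen after its values were seen and not tested, lay at 10.08 to 10.36 and at 8.22 to 9.14.

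Genes of chromosome 8 were shifted upward in this comparison, a grouping chosen after the values were seen. Over the 502 genes of chromosome 8 with a mean of at least 7 on the log2 scale, the median difference of the arrays labelled iPS from brain NSC was 0.45 (1.36-fold), and 90.0% of these genes lay above 0. Of all 940 measured genes of that chromosome, 37 were called higher and 1 lower. The next autosome was chromosome 15, with a median of 0.15. All 3 arrays labelled iPS lay above all 4 of brain NSC (exact permutation p = 0.0286, two-sided, the smallest possible; 0.127 adjusted over 20 chromosomes). Chromosomes 4 and 9, with medians of -0.003 and 0.000, had the same p values in this test. It therefore does not single out chromosome 8 or measure the size of its shift. Taken on each array against brain NSC replicates 1 to 3 and relative to the other autosomes, the shift was 0.42 to 0.43 in the arrays labelled iPS, 0.40 to 0.43 in those labelled iPS-derived NSC and -0.02 to 0.07 in brain NSC. In iPS-derived NSC over brain NSC the chromosome was less uniform. Without that correction for the other autosomes its median was 0.31, 62.5% of its bright genes lay above 0, and 172 genes were called higher and 103 lower. Chromosome 7 stood at 0.25, and chromosomes 14 (-0.697), X (-0.561) and 1 (-0.329) had larger absolute medians than chromosome 8 there. Gene placement followed the RefSeq table of GRCm38.p6.

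**Figure D2:**
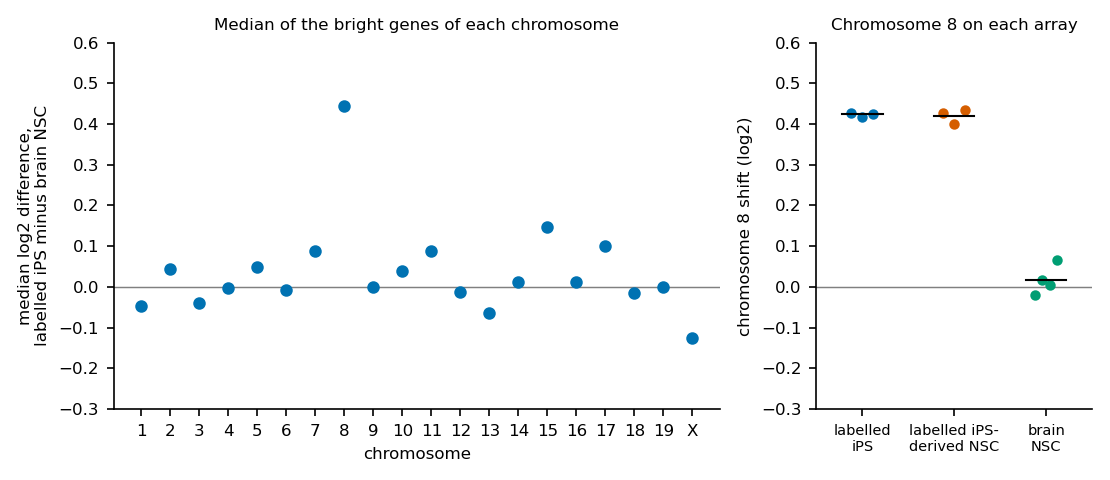
Left, median log2 difference of the arrays labelled iPS from brain NSC over the bright genes of each chromosome; right, shift of the chromosome 8 genes on each array (log2), with a bar at the group mean, for 3, 3 and 4 arrays. Chromosome 8 stands at 0.45 and the next chromosome at 0.15, and the 3 arrays labelled iPS and the 3 labelled iPS-derived NSC lie above the 4 brain NSC arrays.

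The comparison of iPS-derived NSC with iPS asks what changed on differentiation. By their labels, the differentiated cells had high pluripotency genes and low levels of most neural stem cell markers. Dppa2, a gene of undifferentiated embryonic stem cells, was higher in the arrays labelled iPS-derived NSC by 9.45 ± 0.10 (SE, 3 against 3 arrays; 8.38 on its other probe set), the related marker Dppa5a by 8.94 ± 0.10, the Nodal co-receptor Tdgf1 by 8.92 ± 0.09 and the epithelial cadherin Cdh1 by 8.88 ± 0.11. Fabp7 fell by 9.75 ± 0.11, the neural membrane glycoprotein Gpm6a by 8.87 ± 0.11, the extracellular matrix protein Spon1 by 8.32 ± 0.15, the microtubule-associated protein Map2 by 8.25 ± 0.09 and the neuronal pentraxin Nptx1 by 8.05 ± 0.10. The largest adjusted p among these 9 genes was 3.88e-14. This direction is the reverse of what the sample names describe.

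All 26 measured pluripotency genes rose, also when adjusted over the list alone, by 5.89 on average (camera adjusted p = 4.03e-19; 0.00152 with an estimated correlation). Of the 6 reprogramming factors 4 rose, Pou5f1 by 8.62 ± 0.12 and Klf4 by 5.12 ± 0.14 among them, while Sox2 (0.11 ± 0.09) and Myc (-0.44 ± 0.11) were not called; the list's adjusted p was 0.00928 and 0.0764 with an estimated correlation. Of the 26 neural stem cell markers 21 fell, with Fabp7 and the receptor phosphatase Ptprz1 (-7.70 ± 0.19) in the lead, and 1 rose, Prom1 (2.25, chosen after its values were seen), which encodes a surface protein of several stem and epithelial cell types. The mean of this list was -3.92 (adjusted p = 4.64e-13; 0.0298 with an estimated correlation).

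Of 17 epithelial genes 13 rose and 0 fell, Cdh1 and the splicing regulator Esrp1 (5.00 ± 0.14) among them (adjusted p = 1.71e-07; 0.0375 with an estimated correlation). Of 16 mesenchymal genes 8 fell and 5 rose (adjusted p = 0.125), with falls of 5.89 ± 0.14 for the neural cadherin Cdh2 and 5.24 ± 0.12 for the repressor Zeb1. Of 21 DNA methylation and chromatin regulators 14 rose and 0 fell, led by Dnmt3l (7.34 ± 0.12) and the de novo DNA methyltransferase Dnmt3b (6.15 ± 0.13), with an adjusted p of 3.80e-06 and 0.0375 with an estimated correlation. Of 17 germline genes 12 rose, Tex19.1 by 8.30 ± 0.09, and 1 fell, Tdrkh (-2.60, chosen after its values were seen), with an adjusted p of 5.51e-06 and 0.0375 with an estimated correlation. All 11 measured cholesterol synthesis genes fell, by 1.67 on average (adjusted p = 1.22e-06; 0.0415 with an estimated correlation).

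Other lists passed only with the preset correlation. Of 16 astrocyte markers 7 fell, the membrane protein Mlc1 by 6.35 ± 0.31, and 2 rose (adjusted p = 0.0396; 0.116 with an estimated correlation). The mesoderm and endoderm genes (4 of 19 higher, 1 lower; adjusted p = 0.0253) had Gata6, a factor of primitive endoderm, at 3.52 ± 0.12, and the trophectoderm genes (2 of 7 higher; 0.0396) had Eomes at 2.88 ± 0.13 (1.75 on its other probe set, which became the brighter without any 1 of the arrays labelled iPS-derived NSC). The Hedgehog pathway genes had 5 of 9 lower and 1 higher (0.0444), with the surface co-receptor Gas1 at -5.90 ± 0.11, and the immediate early and stress genes had 7 of 15 higher and 1 lower (0.0488), with Jun, the 1 that fell, at -3.89 ± 0.17. For these 4 lists the adjusted p was 0.116 with an estimated correlation. The endothelial and pericyte markers had 3 of 13 higher, Pecam1 at 3.67 ± 0.17 among them (adjusted p = 0.0253; 0.153 with an estimated correlation). Without dim genes the lists of this paragraph did not pass (0.0613 to 0.0918). The Hedgehog list did not pass without iPS-derived NSC replicate 1 (0.0576), and the immediate early list without iPS replicate 2 (0.0631) or iPS-derived NSC replicate 1 (0.0543).

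The remaining 22 lists did not pass with either correlation on the values as deposited. Of 15 feeder fibroblast markers 6 were called higher and 1 lower (adjusted p = 0.0778; 0.0131 without iPS-derived NSC replicate 3); the fibroblast collagen Col3a1 stood 2.95 ± 0.42 higher, but at 0.80 without probe sets that can cross-hybridise. Imprinted genes went both ways, 12 higher and 5 lower of 26 (0.103), with the noncoding RNA Meg3 at 4.85 ± 0.14 (0.26 to 5.01 over its 11 probe sets, and 2.25 to 2.44 without 1 of the arrays labelled iPS-derived NSC) and Phlda2 at 4.44 ± 0.10. Neuron markers had 5 higher and 2 lower of 20 (0.199), with the neuronal tubulin Tubb3 at 5.34 ± 0.14 and Map2 among the lower. The forebrain list had 2 higher and 5 lower of 17 (0.114; 0.0425 without probe sets that can cross-hybridise) with Lhx2 at -5.22 ± 0.18, and the Notch list 1 higher and 6 lower of 14 (0.106) with the glycosyltransferase Lfng at -4.01 ± 0.31. The Wnt targets had 3 higher and 2 lower of 10 (0.254) with the antagonist Dkk1 at 3.96 ± 0.12, the BMP and Id genes 3 higher and 1 lower of 11 (0.199) with Id2 at -4.62 ± 0.11 (-0.58 and not called without probe sets that can cross-hybridise), and the LIF pathway 3 higher of 6 (0.290) with its feedback inhibitor Socs3 at 4.44 ± 0.11. The primed epiblast list had 3 higher and 2 lower of 8 (0.810) with the signalling ligand Nodal at 5.14 ± 0.14, the ependymal list 3 higher and 1 lower of 8 (0.633) with Ak7 at 4.22 ± 0.12, the microglia list 1 of 14, Cd68 at 1.75 ± 0.19 (0.254), and the interferon list 1 higher and 1 lower of 9 (0.667) with Ifit2 at -4.37 ± 0.11. Xist, the RNA that coats the inactive X chromosome, stood 4.92 ± 0.16 higher, 1 of 2 called of 4 X inactivation RNAs (0.190), but at 0.19 without probe sets that can cross-hybridise.

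In 8 lists the median, the mean and the camera direction, which was down in each, differed in sign. The mean was below 0 and the median above it for the oligodendrocyte lineage (-0.74 and 0.25; 2 higher and 4 lower of 16; adjusted p = 0.797), with Olig1 at -6.45 ± 0.11, for hindbrain and spinal cord patterning (-0.25 and 0.24; 1 higher and 6 lower of 26; 0.977), with Hoxa5 at -4.58 ± 0.20, and for Y-linked genes (-0.37 and 0.34; 1 lower of 3; 0.797), the called one being Kdm5d at -2.31 ± 0.11, though at -0.98 and not called with the mean of its 3 probe sets, which ranged from -2.31 to 0.02. The same held for MHC class I and antigen processing (-0.58 and 0.03; 3 lower of 11; 0.254), with B2m, the light chain of MHC class I, at -3.31 ± 0.11, and for CDK inhibitors and p53 targets (-0.17 and 0.20; 3 higher and 3 lower of 13; 0.977), with Cdkn2c at -4.60 ± 0.14. The mean was above 0 and the median below it for glycolysis (0.56 and -0.12; 4 higher and 2 lower of 14; 0.977), with the glucose transporter Slc2a3 at 5.49 ± 0.26, for oxidative phosphorylation (0.08 and -0.09; 1 higher of 19; 0.484), with Cox7a1 at 4.46 ± 0.12, and for the cell cycle (0.04 and -0.05; 1 higher and 1 lower of 20; 0.810), with the cyclin Ccne1 at 2.10 ± 0.10.

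Thus 13 of 35 lists passed, and 6 did with an estimated correlation. In all, limma called 4598 of 18193 genes (25.3%), 1970 higher and 2628 lower in the arrays labelled iPS-derived NSC. The median difference of all genes was 0.12.

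**Figure D3:**
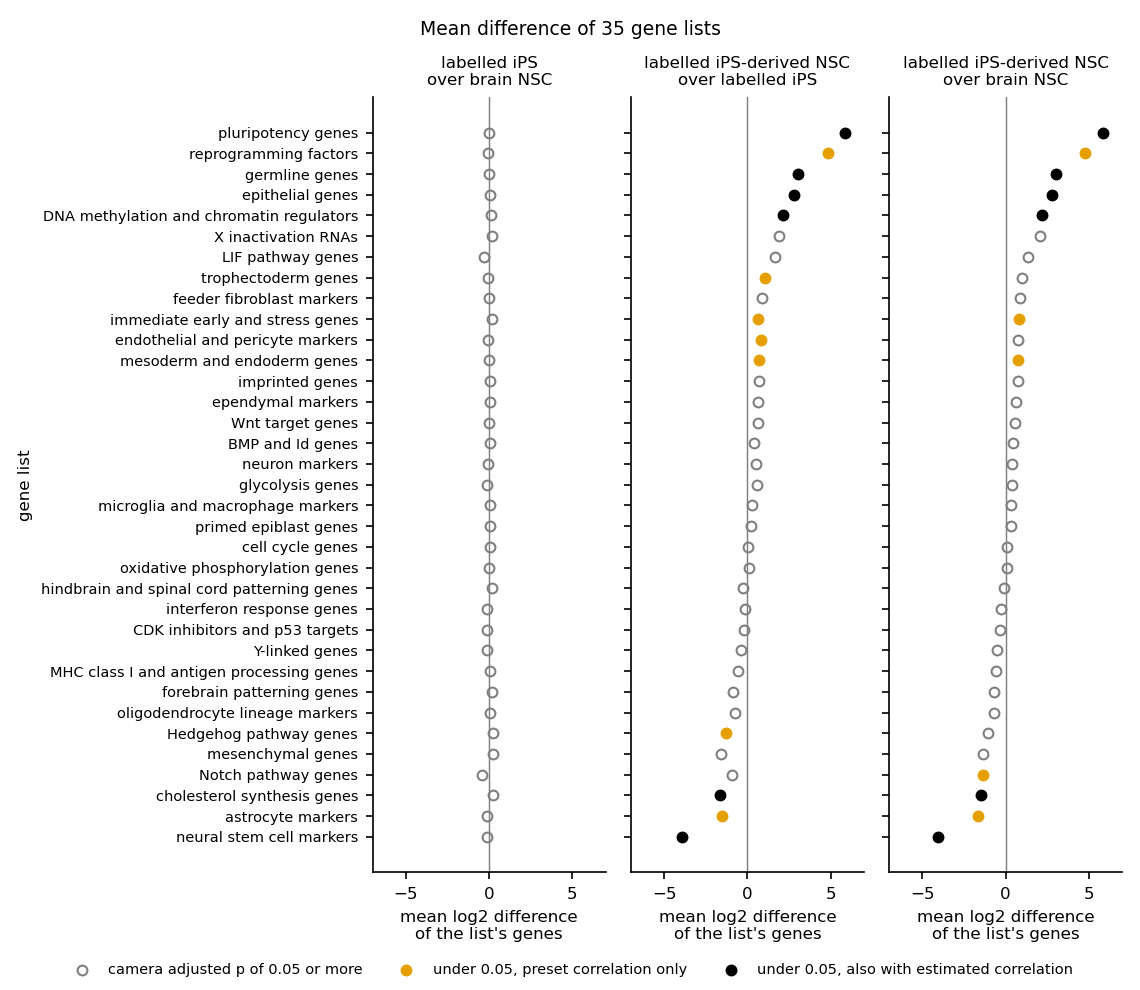
Mean log2 difference of each of the 35 gene lists in the 3 comparisons, with filled points for lists past the camera threshold (black where they also pass with an estimated correlation) and open points for the others. The labelled iPS over brain NSC panel holds 0 filled points, and the pluripotency genes (5.89 and 5.86) and neural stem cell markers (-3.92 and -4.06) lie at the ends of the other panels.

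The comparison of iPS-derived NSC with brain NSC asks how close the differentiated cells came to the brain cells. By label, most neural stem cell markers were lower in them and the pluripotency genes higher, while some neural genes were higher, such as the neuron markers Tubb3 and Stmn2 (5.14 and 4.91, Stmn2 chosen after its values were seen). Fabp7 fell by 10.02 ± 0.10 (SE, 3 against 4 arrays), Gpm6a by 8.64 ± 0.11, Map2 by 8.48 ± 0.09, the integrin subunit Itgb8 by 8.33 ± 0.12 and the membrane glycoprotein Gpm6b by 8.10 ± 0.10. Dppa2 rose by 9.43 ± 0.09, Cdh1 by 8.94 ± 0.10, Zfp42 by 8.94 ± 0.10, the ribosomal protein gene Rps4l by 8.81 ± 0.14 and Tdgf1 by 8.78 ± 0.09. Among the factors, Pou5f1 was higher by 8.74 ± 0.12 and Klf4 by 4.85 ± 0.13, and Sox2 (-0.02 ± 0.09) and Myc (0.03 ± 0.10) were not called. Here too the direction goes against what the names describe.

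Of 26 neural stem cell markers 23 fell and 1 rose, also when adjusted over the list alone, with Ptprz1 at -7.73 ± 0.18 (camera adjusted p = 2.63e-14; 0.0229 with an estimated correlation). All 26 pluripotency genes rose (4.44e-18; 0.00182 with an estimated correlation). Of 16 astrocyte markers 8 fell and 2 rose, with Mlc1 at -6.31 ± 0.28 and the brain aldolase Aldoc at -5.85 ± 0.14 (adjusted p = 0.00717; 0.0633 with an estimated correlation). Of 16 oligodendrocyte lineage markers 3 fell and 2 rose (0.749), the neural transcription factors Olig1 by -6.19 ± 0.10 and Olig2 by -5.93 ± 0.18 among those that fell. In the forebrain list, 4 of 17 fell and 2 rose (0.119; 0.0492 without probe sets that can cross-hybridise), Pax6 by -4.18 ± 0.12 and Lhx2 by -3.92 ± 0.17. In the hindbrain and spinal cord list, 3 of 26 fell and 1 rose (0.912), Hoxa5 at -4.46 ± 0.19 and Gbx2 at 3.12 ± 0.18, and the mean was -0.10 while the median was 0.22 and camera's direction was up. Imprinted genes were 12 higher and 6 lower of 26 (0.114), with Phlda2 at 4.56 ± 0.09 and Meg3 higher by 4.50 on its brightest probe set.

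Epithelial genes (14 of 17 higher; adjusted p = 1.78e-07; 0.0457 with an estimated correlation), chromatin regulators (14 of 21 higher, Dnmt3l at 7.34 ± 0.11; 2.79e-06; 0.0418 with an estimated correlation), germline genes (13 higher and 1 lower of 17; 1.97e-05; 0.0457 with an estimated correlation) and cholesterol synthesis genes (9 of 11 lower, Cyp51 at -2.03 ± 0.11; 2.79e-06; 0.0497 with an estimated correlation) passed here as well. Reprogramming factors (4 of 6 higher; 0.00695; 0.0633 with an estimated correlation), mesoderm and endoderm genes (5 of 19 higher; 0.0299; 0.141 with an estimated correlation), Notch pathway genes (8 lower and 1 higher of 14, Lfng at -4.17 ± 0.29; 0.0157; 0.0841 with an estimated correlation) and immediate early and stress genes (7 higher and 1 lower of 15; 0.0157; 0.0726 with an estimated correlation) passed only with the preset correlation. Thus 11 of 35 lists passed, and 6 did with an estimated correlation. Feeder fibroblast markers had 7 higher and 2 lower of 15, with the collagen Col1a2 at 2.97 ± 0.28 (0.0716; 0.0129 without iPS-derived NSC replicate 3). The Hedgehog list (0.0716) passed without probe sets that can cross-hybridise (0.0387), and the endothelial and pericyte list (0.0588) without iPS-derived NSC replicate 1 (0.0316) or 2 (0.0495) or brain NSC replicate 1 (0.0469). Of the other named genes, B2m, Ifit2, Cdkn2c, Gas1 and Jun were lower by 3.52 or more, and Nodal, Slc2a3, Cox7a1, Ak7 and Socs3 were higher by 4.11 or more. Median, mean and camera direction again differed in sign for the oligodendrocyte, Y-linked, MHC class I, CDK inhibitor, glycolysis, oxidative phosphorylation and cell cycle lists, with adjusted p values from 0.343 to 0.825.

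In all, limma called 4618 genes (25.4%), 2064 higher and 2554 lower, and the median difference of all genes was 0.13. The balance of directions depended on the scaling. Of the called genes 51.6%, 42.8% and 44.7% were higher in the 3 comparisons in the order given here. These were 47.2%, 48.3% and 49.3% after quantile normalization, and 54.8%, 40.2% and 43.1% with each array centred on its median. Of the 118 calls of named genes, 28 (21 genes) had another probe set under 2-fold in that direction. In iPS over brain NSC these included Pcdh7 (-0.31), Eya1 (-0.28) and Pfkp (-0.29). In iPS-derived NSC over iPS they included Spon1 (-0.38), Zeb1 (-0.05), Gas1 (-0.08) and Gata6 (0.58), and in iPS-derived NSC over brain NSC Pax6 (0.00), Hoxa5 (-0.06) and Col1a2 (0.06). Of the 4618 genes, 3913 were also called in the same direction between the arrays labelled iPS-derived NSC and those labelled iPS, 1688 higher and 2225 lower, with 0 in opposite directions. Independent lists of these sizes would share 223 and 369. Simulated unchanged groups against the same arrays shared 0, but at most 0.01 genes were called in them on average, so this 0 is no benchmark for the count. The correlation of the differences across genes was 0.965 (simulated 0.533) and their covariance 1.70 (simulated 0.0101). Genes are not independent replicates. Both comparisons share the arrays labelled iPS-derived NSC, and the groups these were set against lay close together (root mean square difference 0.35). A large overlap follows largely from this, so independent lists are no benchmark for it either.

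Of the 335 genes called between the arrays labelled iPS and brain NSC, 132 (39.4%) were called in the same direction between those labelled iPS-derived NSC and brain NSC, 32 higher, such as Rest, Kit and Otx2, and 100 lower, such as Hes5, and 65 were called in the opposite direction, such as Lhx2, Twist1, Tgfb2 and Id2, lower here, and Apoe, Plagl1 and Pfkp, higher here. Several of these examples are not firm in iPS over brain NSC. Rest, Tgfb2, Id2, Plagl1 and Pfkp had another probe set under 2-fold there, and the call of Otx2 was lost in several settings. Independent lists would share 19.6 higher and 22.7 lower, and 42.7 in opposite directions. The simulated unchanged groups shared 0, which is no benchmark here either, as 0 genes were called in them. The correlation across genes was 0.127 (simulated 0.429) and the covariance 0.059 (simulated 0.0076). With the 4 brain NSC arrays split into 2 and 2, so that the comparisons shared no array, the share was 27.0% to 45.4% over 6 splits, with 113 to 172 genes called in the same direction and 49 to 146 in the opposite direction. In the split with the lowest share these were 172 and 146.

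On the line from the arrays labelled iPS (0.06 ± 0.05, SD, n = 3) to brain NSC (0.94 ± 0.31, n = 4), the arrays labelled iPS-derived NSC stood at 0.52 ± 0.09 (n = 3), with no difference from brain NSC detected (exact permutation p = 0.114, two-sided; smallest possible 0.0286). They lay far off this line: the root mean square difference was 1.32 from brain NSC and 1.33 from the arrays labelled iPS, against 0.35 between these. Arrays about equally far from both ends fall near the middle of the line. The 0.52 therefore does not show a state between the 2 groups. Brain NSC replicate 4 stood at 0.48, and the other brain NSC arrays at 1.02 to 1.16. Replicate 4 thus lay within the 0.447 to 0.628 of the arrays labelled iPS-derived NSC, which kept the test from its smallest p. The test does not show likeness to brain NSC, against which 4618 genes were called.

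The correlation of arrays across genes also put the arrays labelled iPS close to brain NSC. It averaged 0.988 between the arrays labelled iPS and brain NSC, and 0.861 and 0.858 between those labelled iPS-derived NSC and these groups, with 0.994 to 0.998 within groups. Genes are not independent replicates, so these values describe the arrays. The control transcripts added before labelling averaged 7.23 ± 0.17 in the arrays labelled iPS, 9.07 ± 0.22 in those labelled iPS-derived NSC and 8.77 ± 0.40 in brain NSC. The first and last differed with an exact permutation p of 0.0286 (two-sided; 0.200 adjusted over 12 tests of array quality). No batch is named in the labels, so a batch of arrays and the group cannot be told apart.

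**Figure D4:**
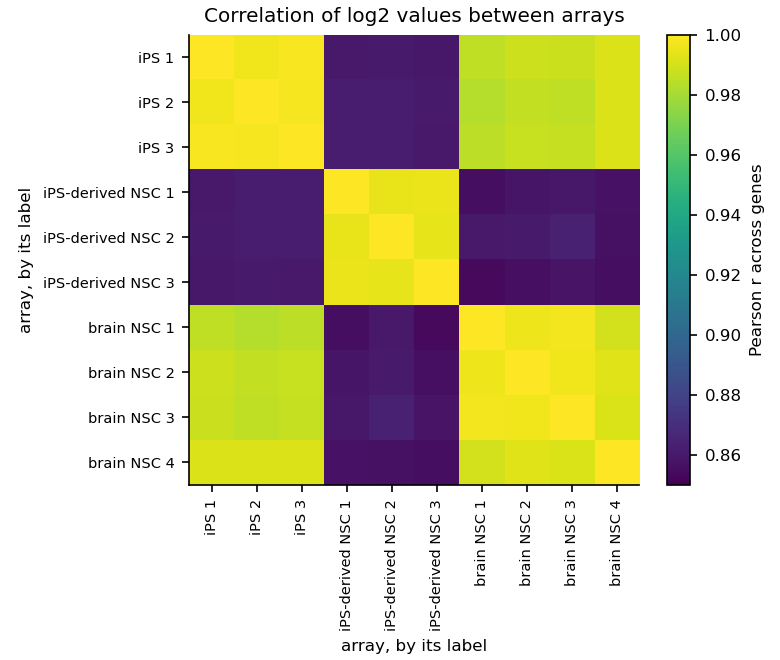
Pearson correlation across genes of the log2 values of each pair of the 10 arrays, named by label and replicate. The arrays labelled iPS and brain NSC form 1 block (mean 0.988), the arrays labelled iPS-derived NSC form another, and brain NSC replicate 4 is as close to the arrays labelled iPS (0.992) as to the other brain NSC arrays (0.991).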

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

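The tests of the identity of brain NSC replicate 4 and of its labelling controls were chosen only after the result was seen. The prediction for mixed RNA and the rule for single arrays were set before. That prediction covered only the median share over genes higher in the arrays labelled iPS. The quartiles and the genes lower there were not part of it.

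In 4 of the 79 named genes, brain NSC replicate 4 stood apart from the other 3 brain NSC arrays. Dhcr7 stood at 11.717 (others 10.163 to 10.373), Lhx2 at 7.762 (others 6.970 to 7.066), Spon1 at 12.324 (others 11.673 to 11.727) and Itgb8 at 11.251 (others 11.568 to 11.617). Chance sets an array apart in about 5% of such groups, so 4 of 79 genes is near the chance share, but all 4 fell on the same array.

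Replicate 4 of brain NSC was also as close to the arrays labelled iPS (mean correlation 0.9919) as to the other brain NSC arrays (0.9913), and 2 of the 35 splits of these 7 arrays called at least as many genes as the labelled groups (335), the highest other being 355 with replicate 4 moved to the arrays labelled iPS. Chance is therefore not excluded by this count for the comparison of iPS with brain NSC, and the split points to a structure that follows replicate 4. An array of the cells labelled iPS is argued against, because its chromosome 8 genes were shifted by 0.066 against 0.418 to 0.428 in the arrays labelled iPS. The prediction for RNA of these cells mixed into replicate 4 rested on genes at least 4-fold higher in the arrays labelled iPS. Over these 15 genes the array held a median of 0.0397 of the difference, with Cd93 at 0.015. By that prediction this argues against mixing, but the quartiles were -0.0153 and 0.398. Over the 23 genes at least 4-fold lower, outside the prediction, the median was 0.277 (quartiles 0.0691 and 0.416). A mixture alone would give all genes 1 common share. The shares ran from -0.118 to 1.53 in the higher genes and from -0.156 to 0.560 in the lower. This spread argues against mixing as the only cause. Mixing beside other differences in replicate 4 stays open. A difference in culture or array batch may remain as well: its labelling controls, at 8.310, lay below the 8.601 to 9.235 of the other brain NSC arrays and 36.3% of the way to the 7.227 of the arrays labelled iPS, which does not decide, and no biological explanation was tested because the labels give the brain NSC samples no difference.

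Among the 9160 probe sets without a gene name in the annotation used here, 120 were called between the arrays labelled iPS and brain NSC, 774 between those labelled iPS-derived NSC and iPS, and 787 between those labelled iPS-derived NSC and brain NSC. Each is a smaller share than among the 18193 genes, of which 1.84%, 25.3% and 25.4% were called. The control probe set for the B2 repeat, a short interspersed element of the mouse genome, averaged 11.963 in the arrays labelled iPS-derived NSC, while the single arrays of both other groups lay between 9.440 and 9.868.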

How the results depend on the processing

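The counts without the genes of chromosome 8 were chosen only after the result was seen; all other alternatives were planned. Besides the values as reported, 28 settings were run, 10 of them leaving out 1 array each. Some settings, such as other thresholds and variance models, gave counts of calls alone, without named genes or lists. Named genes with no probe set left in a setting could not be followed there. Of the 118 calls among the 126 named gene results, 13 were lost and 3 had their sign turned in at least 1 setting that covered them. Of the list results in the settings that covered lists, 1437 kept their side of the threshold and camera direction. Another 36 no longer passed, 9 passed only then and 58 that did not pass changed camera direction. The signal of the probe sets over their background limits dim genes most. Background correction, slide and scan date were not run, since scanner files were not used here. The cause was not tested for the changes given here, except where the construction of the setting shows it.

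The count of genes called between the arrays labelled iPS and brain NSC (335) was 223 with the mean of the probe sets of a gene, 183 against a minimum of 1.5-fold and 3704 with no minimum fold. With no minimum fold the counts for iPS-derived NSC over iPS and over brain NSC were 11123 and 11415. Counted as probe sets, of which more are tested, 833, 8275 and 8330 were called. Leaving out 1 array gave 298 to 539, the highest without brain NSC replicate 4. The other counts ranged from 4574 to 4638 and from 4581 to 4700. Without the genes of chromosome 8 the counts were 297, 4339 and 4343. The position of the arrays labelled iPS-derived NSC was 0.412 after quantile normalization.

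With the replicate number as a block, a paired fit, 537 genes were called between the arrays labelled iPS and brain NSC, and 4599 and 4658 in the others. The numbers did not pair the samples: 1 of 9 pairs correlated above 0.1 and 2 of 9 correlated best with their own number. Brain NSC replicate 4 has no partner, so the block in effect leaves it out. In that fit the adjusted p was 0.968 for the neural stem cell markers and 0.989 for the epithelial genes, each with camera's direction turned though the mean difference kept its sign, and neither passed in this comparison under any setting run.

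Among the lists in iPS-derived NSC over brain NSC, the astrocyte markers had an adjusted p of 0.0633 with an estimated correlation, and the forebrain genes 0.0492 without probe sets that can cross-hybridise. The hindbrain and spinal cord genes turned direction without passing, at 0.848 after quantile normalization and 0.495 without dim genes (0.830 to 0.981 leaving out 1 array). In iPS over brain NSC the epithelial genes turned at 0.882 without probe sets that can cross-hybridise. Leaving out 1 array, camera's direction turned in at least 1 case for the neural stem cell markers (0.737 to 0.997), the chromatin regulators (0.565 to 0.999) and the imprinted genes (0.841 to 0.993).

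Plagl1 in iPS over brain NSC was at 0.064 without probe sets that can cross-hybridise. Leaving out 1 array, Zbed6 ranged from -0.339 to 2.396 and Rest from -0.088 to 1.377, because another probe set of the gene became the brightest without 1 of the arrays labelled iPS. The same occurred for Dppa2, Eomes and Meg3 without 1 of the arrays labelled iPS-derived NSC, and they stayed called in iPS-derived NSC over iPS.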

Other observations

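All tests of the exchanged names, of undifferentiated cells and of chromosome 8 were chosen only after the result was seen; the counts of other splits were not.

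Within the fixed lists, some members outside the naming rule, chosen after their values were seen, differed between the arrays labelled iPS-derived NSC and iPS, by labels that the markers contradict; they were not tested as groups. Of 8 Polycomb genes and partners in the list of chromatin regulators, Eed rose by 2.62 ± 0.10 (SE, 3 against 3 arrays), Jarid2 by 3.05, Mtf2 by 2.62, Cbx7 by 3.11 and Phc1 by 1.86, while Suz12 (0.65), the catalytic subunit gene Ezh2 (-0.06) and Kdm2b (0.95) were not called. The DNA demethylating enzymes Tet1 and Tet2 rose by 2.42 and 2.74, and Dnmt3a, a de novo DNA methyltransferase, by 4.64, while Dnmt1, at -0.38, was not called. Neuronal genes went both ways: Stmn2, Ina and Nefl, which encode a microtubule regulator and intermediate filaments, rose by 4.76, 2.97 and 3.10, and the growth cone protein Gap43 fell, from 7.90 to 5.41. Meg3, Rian and Mirg, noncoding RNAs of 1 imprinted cluster, rose by 4.85, 3.45 and 1.74, and Dlk1, a protein-coding gene of that cluster, by 1.41; Meg3 depended on its probe set, from 0.26 to 5.01.

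A candidate explanation of the high pluripotency genes in the arrays labelled iPS-derived NSC is that the names of the iPS and iPS-derived NSC triplets were exchanged. The arrays labelled iPS differed from brain NSC by a mean of -0.034 over the 26 genes, and 26 of 26 were called higher in the arrays labelled iPS-derived NSC, but these values are the pattern itself and do not test the explanation. A minority of undifferentiated cells among differentiated ones is argued against, since the 24 neural stem cell markers bright in brain NSC kept a median of 0.0567 of their brain NSC level there (quartiles 1.99% and 11.5%). Values outside the pluripotency list also went against both names. Of the 26 neural stem cell markers, 21 were lower in the arrays labelled iPS-derived NSC than in those labelled iPS, and 1 was higher. The correlation with brain NSC averaged 0.988 for the arrays labelled iPS and 0.858 for those labelled iPS-derived NSC. These values argue against both names as they stand. Why names and markers disagree, through exchanged names, exchanged table columns or otherwise, stays open. Of the 35 splits of the arrays labelled iPS-derived NSC and brain NSC, only the labelled 1 called as many genes (4618, highest other 2709). This share, 0.0286, is the smallest these splits allow. It makes chance unlikely only if the samples are independent, which the labels do not say. Of the 10 splits with the arrays labelled iPS, 1 did (4598, highest other 0), too few splits for a share under 0.05.

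The chromosome 8 shift may reflect a gain of the whole chromosome in the cells of the arrays labelled iPS, whichever way they are named. In line with this, the medians of 6 consecutive sixths of its bright genes in iPS over brain NSC ran from 0.270 to 0.532, each above the next autosome and below the 0.585 of 3 copies against 2. A few strongly changed genes are argued against by the 90.0% of its genes above 0. For array batch or normalization, the prediction was an equally large median on another autosome, and the largest was 0.147. Chromosome 8 had been picked for its high median before this prediction was written. A lower median elsewhere was thus given in advance, and the comparison does not decide on batch or normalization. Of 10000 random gene lists of like brightness, 0 reached 0.445 (highest 0.093). These lists cannot test batch or normalization, because chromosome 8 was chosen after its median was seen. The autosome at 0.147 also exceeded the highest of them, so they do not single out chromosome 8. In iPS-derived NSC over brain NSC the sixths ran from -0.426 to 0.632, 1 below 0 and 1 above 0.585, and the median of chromosome 14 was -0.697, so a gain in the arrays labelled iPS-derived NSC is left open. DNA copy number was not analysed here, and this remains a hypothesis.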
